A study of Mus musculus with 7 samples.

How the data were processed

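RNA of 7 cultured fetal mouse kidneys was measured by sequencing. Per the labels, the strain was C57BL/6 and all 7 libraries carried activated beta-catenin, the effector of canonical Wnt signalling; 3 were E2-2 deleted and 4 were E2-2 wildtype. E2-2 is a basic helix-loop-helix transcription factor of the E protein class, encoded in the mouse by Tcf4. Per the labels' protocols, kidneys were dissected at 10.5 days post coitum and grown in culture for 3 to 4 days, and the pregnant mice received tamoxifen at 10.5 days post coitum, at 2 mg per 40 g of body weight. Which library was cultured for 3 and which for 4 days is not given in the labels. Total RNA was extracted with Trizol, poly-A RNA was selected and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Replicate numbers within each genotype follow the order of deposit and pair no samples. The labels do not say whether each library came from a separate animal or culture, so p-values measure only the spread between these samples, which may be technical.

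The authors deposited 1 table per library with an FPKM value per gene, per the file headers. FPKM stands for fragments per kilobase of transcript, scaled to the mapped total of the library. The authors' tables also give a lower and an upper bound of the interval of each FPKM and a status of the estimate, per the file headers. CASAVA 1.8.2, TopHat2 2.0.4 and Cufflinks 2.0.2 are named in the submitters' processing notes, without their roles; the table columns are those of a Cufflinks gene table. The genome build and the gene annotation are not given in the sources used here. Of 20982 entries whose symbol is in a GRCm38 gene table, 165 had the same start and end there and 294 shared a start or an end. Coordinates are therefore printed as the deposited tables give them, counted from 1, and no build is named for them. Each table had 23699 entries. In 1 table (E2-2 deleted replicate 2), 25 gene symbols had been turned into dates, as a spreadsheet does; the loci were identical entry by entry in all 7 tables, so the symbols were taken from another table.

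The deposited tables hold no read counts. The width of the deposited interval of a gene's FPKM gave an inferred number of fragments, as the square of 2 times the FPKM divided by the distance from the FPKM to the upper bound. This relation is an inference from the values. Among genes with a single transcription start and under 300 inferred fragments, 78.9% to 80.2% of these numbers lay within 0.05 of a whole number, against 10% by chance. The inferred depth was 14.6 to 26.6 mega-fragments (M) per library. FPKM removes most of a difference in depth from the values, but a shallower library measures a low gene less precisely.

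Entries of one symbol were summed (248 symbols had more than 1). Genes with a failed or low-data status in any library, and small RNAs shorter than a library fragment, were left out. Of the 22367 genes that remained, the 13466 with a mean of at least 1 FPKM over the 7 libraries were tested. The values were taken as log2(FPKM + 1) with no further scaling, so a log2 difference understates the change of a gene near 1 FPKM. The genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model over all 7 libraries, empirical Bayes with a mean-variance trend, 2-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), and differences are E2-2 deleted minus E2-2 wildtype. Single values were also compared by an exact 2-sided permutation test over the 35 ways of splitting 7 libraries into 3 and 4; the smallest p it can give is 0.0286. A count-based test was planned in case the tables held counts and was not run, since they hold FPKM.

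A set of 24 gene lists covered Wnt/beta-catenin targets, E proteins and Id factors, kidney lineages, other cell types a kidney rudiment could hold, and stress and growth programmes. Lists with at least 5 tested members (22 of the 24) were tested with camera of limma at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 22 lists. The size of a list's difference is that of its mean log2(FPKM + 1) per library. Alternatives for the lists were camera with an estimated correlation, fry, and an exact permutation test of the list means. Adjusted over the 22 lists, the permutation test could pass only if many lists reached its smallest p of 0.0286 together. The sex-linked list was kept out of the tests and read per library. Genes named in the text were chosen by a fixed rule: Tcf4 and the other E protein and Id genes; Ctnnb1, Axin2, Lef1, Six2, Wt1, Cdh1 and Vim; the 12 largest positive and 12 largest negative differences past the threshold with non-overlapping groups, filled, where fewer passed, with the non-overlapping genes of smallest p; and the 2 to 4 members of smallest p of each list described. Predicted genes and clones were passed over in the lists of 12. Of the genes this rule names, 2 are not reported here. The groups, the test, the lists, the rule for named genes and the alternatives were set before the data were examined, except those named as added.

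Each result was computed again with a pseudocount of 0.1, with no filter on low values, with a minimum of 5 FPKM, with median-of-ratios scaling and with quantile normalization. Further alternatives were a robust variance fit and fits with a weight per library, with the 2-letter file-name prefix (BI or BM) as a term, with the highest entry of each symbol in place of the sum, with small RNAs kept, and with each library left out in turn. A fit with the sex read from Xist and Y-linked genes as a term, quantile normalization without ribosomal protein genes, the exact permutation test of list means, and all alternatives for the correlation between libraries were added after the data had been seen. A melanocyte list and a tooth and enamel list were also put together after the genes of smallest p had been seen, and were kept out of the 22 lists. The prefix is a feature of the deposited names; its meaning is not given in the labels.

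The gene test was tested on simulated data made for this comparison, with 50 genes changed at each of 4 sizes among 13466. On the residuals of the real libraries it recovered 68% of genes changed by 1 on the log2 scale and 90% of those changed by 2. It recovered 98% of those changed by 3 and 100% of those changed by 4, with 0 false calls. The genotype means had been made equal in these residuals, so the 0 false calls were fixed in advance. Each changed gene then differed by exactly the change put in, so these shares do not measure the power in the real libraries. On independent noise with each gene's own spread, the shares were 64%, 88%, 94% and 98%, with 11 false calls. That noise was independent between genes, and the many changed genes put in made the adjusted threshold easier to reach. These shares therefore do not measure the power in the real libraries either. There Slpi, with a difference of 5.03, had a limma adjusted p of 0.795.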

Results

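Transcript levels were measured in 7 cultured fetal mouse kidneys in which beta-catenin was activated, 3 of them E2-2 deleted and 4 E2-2 wildtype. The comparison asks how the transcripts of a kidney with activated beta-catenin differ when E2-2 is also deleted. Levels are FPKM, given as mean ± SD over the libraries of a genotype (n = 3 deleted, n = 4 wildtype), and differences are on the log2(FPKM + 1) scale. The inferred depth, in mega-fragments (M), was 21.4, 17.7 and 24.9 M in E2-2 deleted replicates 1 to 3 and 18.4, 14.6, 26.6 and 23.1 M in E2-2 wildtype replicates 1 to 4. The deposited names of 3 libraries begin with BM (E2-2 deleted replicate 3, E2-2 wildtype replicates 3 and 4) and those of the other 4 with BI, and differences within each prefix are given for each list, for the genes described first, and for named genes whose sign turns between the prefixes. The BM prefix holds a single deleted library. Which library was cultured for 3 and which for 4 days is not given in the labels, so culture time was not compared.

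Transcripts of Tcf4, the gene that encodes E2-2, were present in every deleted library. The FPKM of Tcf4 (chromosome 18, 69504146 to 69847621) was 33.5, 41.7 and 42.0 in the deleted libraries and 48.8, 58.1, 28.7 and 39.2 in the wildtype libraries. The means were 39.1 ± 4.85 (SD, n = 3) against 43.7 ± 12.6 (SD, n = 4). The difference was -0.12 (SE 0.23, 95% confidence interval -0.65 to 0.41; limma adjusted p = 0.885, exact permutation p = 0.743), within the spread between replicates. It was -0.50 within BI and 0.31 within BM, and 0.03 without E2-2 wildtype replicate 2. The labels do not give the deleted exons, and a whole-gene FPKM misses the loss of a few exons, so this value does not check the genotype.

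Among the partners of E2-2, the inhibitors Id1 and Id3 were lower in every deleted library than in any wildtype library. Id proteins bind E proteins and keep them from DNA. Id1 (chromosome 2, 152562010 to 152563146) was at 63.9 ± 8.46 FPKM (SD, n = 3) against 90.7 ± 8.59 (SD, n = 4), a difference of -0.50 (SE 0.13; -0.65 within BI, -0.25 within BM). Id3 (chromosome 4, 135699737 to 135701307) was at 199 ± 12.3 (SD, n = 3) against 283 ± 40.8 (SD, n = 4), a difference of -0.49 (SE 0.15; -0.36 and -0.66). Both genes passed the limma threshold when adjusted over the list alone (smallest adjusted p = 0.0311) and neither passed over all genes tested (adjusted p = 0.795). Id2 differed by -0.36 (SE 0.16) and Id4 by 0.30 (SE 0.17), and the E protein genes Tcf12 and Tcf3 by 0.29 (SE 0.13) and -0.34 (SE 0.20), none of them past either adjustment. The differences of Id2, Id4 and Tcf3 were -0.22, 0.11 and -0.11 without deleted replicate 2, and that of Tcf3 was -0.53 without deleted replicate 1. The 7 genes together differed by -0.17 (SE 0.04; -0.25 within BI, -0.07 within BM), with a camera adjusted p of 0.131 at the preset correlation (0.620 with an estimated correlation). Without deleted replicate 2 the list passed at 0.0283, in a range of 0.0283 to 0.491 over the alternatives that kept the preset test. Their exact permutation p was 0.0286, the smallest possible, or 0.210 adjusted over the 22 lists.

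**Figure D1:**
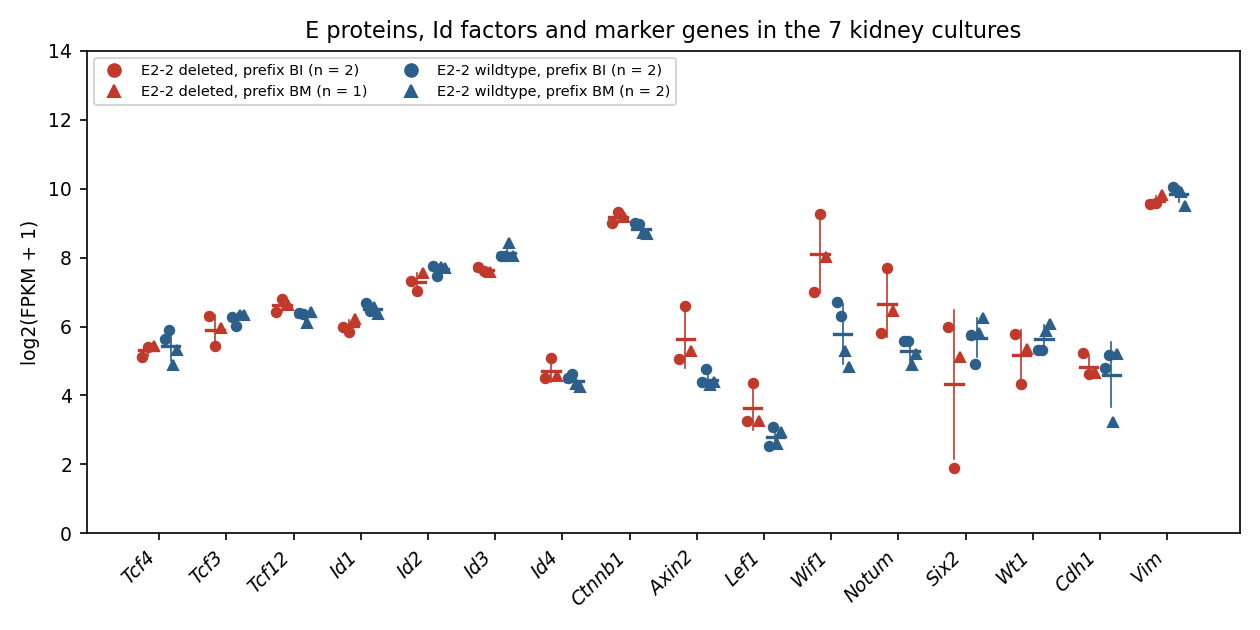
Expression of E protein, Id and marker genes as log2(FPKM + 1) in each of 3 E2-2 deleted (red) and 4 E2-2 wildtype (blue) libraries; circles are prefix BI, triangles prefix BM, and bars give the mean and SD of a genotype. Id1 and Id3 are lower, and Axin2, Lef1, Wif1 and Notum higher, in all 3 deleted libraries than in any wildtype library, while Tcf4 overlaps and Six2 is low in 1 deleted library.

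Slpi, a secreted protease inhibitor, led the genes that were higher in all 3 deleted libraries, and none of them passed the threshold. Slpi (chromosome 2, 164179806 to 164182243) was at 140 ± 144 FPKM (SD, n = 3) against 2.98 ± 2.87 (SD, n = 4), a difference of 5.03 (SE 0.81; 4.36 within BI, 5.31 within BM; adjusted p = 0.795). Trpm1, a cation channel of melanocytes and retina, was at 18.8 ± 11.2 against 2.10 ± 1.31, and Slc24a5, an exchanger of pigment organelles, at 14 ± 4.10 against 5.80 ± 1.29. Klk4, a protease of maturing enamel, was at 5.77 ± 1.85 against 0.847 ± 0.634. Fmod, a collagen-binding proteoglycan, was at 43.5 ± 29.7 against 5.76 ± 2.68, and Igfbp6, which binds insulin-like growth factors, at 101 ± 84.0 against 12.8 ± 6.82. Ptgds, a prostaglandin D synthase, was at 15.3 ± 5.99 against 3.82 ± 1.62, and the peptide hormone gene Pyy at 6.22 ± 4.90 against 0.475 ± 0.406. The somatostatin receptor gene Sstr2, the ion channel gene Accn3, the lysozyme-like gene Lyg2 and the neuropeptide gene Npb differed by 1.84, 1.95, 1.63 and 1.05. Deleted replicate 2 had the highest level of all of these genes except Slc24a5 and Npb. Without it the means of Slpi, Igfbp6, Pyy and Fmod in the deleted libraries were 56.5, 52.3, 3.40 and 27.1 FPKM. Those of Accn3 and Sstr2 fell from 5.48 and 6.51 to 3.17 and 4.23 FPKM. The mean of Slpi in the wildtype libraries was 1.95 FPKM without wildtype replicate 1. Within BI these 12 genes differed by 0.80 (Npb) to 4.36 (Slpi) and within BM by 1.45 (Npb) to 5.31 (Slpi). The genes were chosen for groups that did not overlap, so a positive sign within each prefix was fixed in advance.

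Rec8, a cohesin subunit of meiosis (chromosome 14, 56237003 to 56244232), led the genes that were lower in all 3 deleted libraries. It was at 2.27 ± 0.0968 FPKM (SD, n = 3) against 8.06 ± 2.66 (SD, n = 4), a difference of -1.42 (SE 0.24; -1.51 within BI, -1.36 within BM; adjusted p = 0.795). Gja4, a gap junction protein of arterial endothelium, was at 13.1 ± 2.19 against 25.1 ± 7.34. F2rl3, a thrombin receptor, was at 1.45 ± 0.430 against 3.72 ± 0.862, and Itga9, an integrin subunit, at 22.6 ± 3.77 against 30.4 ± 2.00. Rarres1, a retinoic acid response gene, differed by -0.96 (SE 0.20) and Prr5, a subunit of an mTOR complex, by -0.59 (SE 0.13). Plscr2, Clca5, Fbxl15, Sntg2, the p53 target Aen and Id1 made up the other 6, with differences of -0.94 (Clca5) to -0.43 (Aen). Within BI these 12 genes differed by -1.51 (Rec8) to -0.35 (Itga9) and within BM by -1.36 (Rec8) to -0.25 (Id1). Here too the choice of groups that did not overlap fixed the negative sign within each prefix.

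With limma, 0 of the 13466 genes passed an adjusted p of 0.05, and 0 passed 0.1; the smallest adjusted p was 0.732. At an unadjusted p under 0.05 there were 605 genes, 443 higher and 162 lower in the deleted libraries, where chance gives 673.3. That count was 250 without E2-2 deleted replicate 2, 336 without E2-2 wildtype replicate 4 and 1473 without E2-2 deleted replicate 1. Every deleted library lay above every wildtype library in 382 genes (2.84%) and below in 276 (2.05%), where chance gives 2.86% in each direction.

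**Figure D2:**
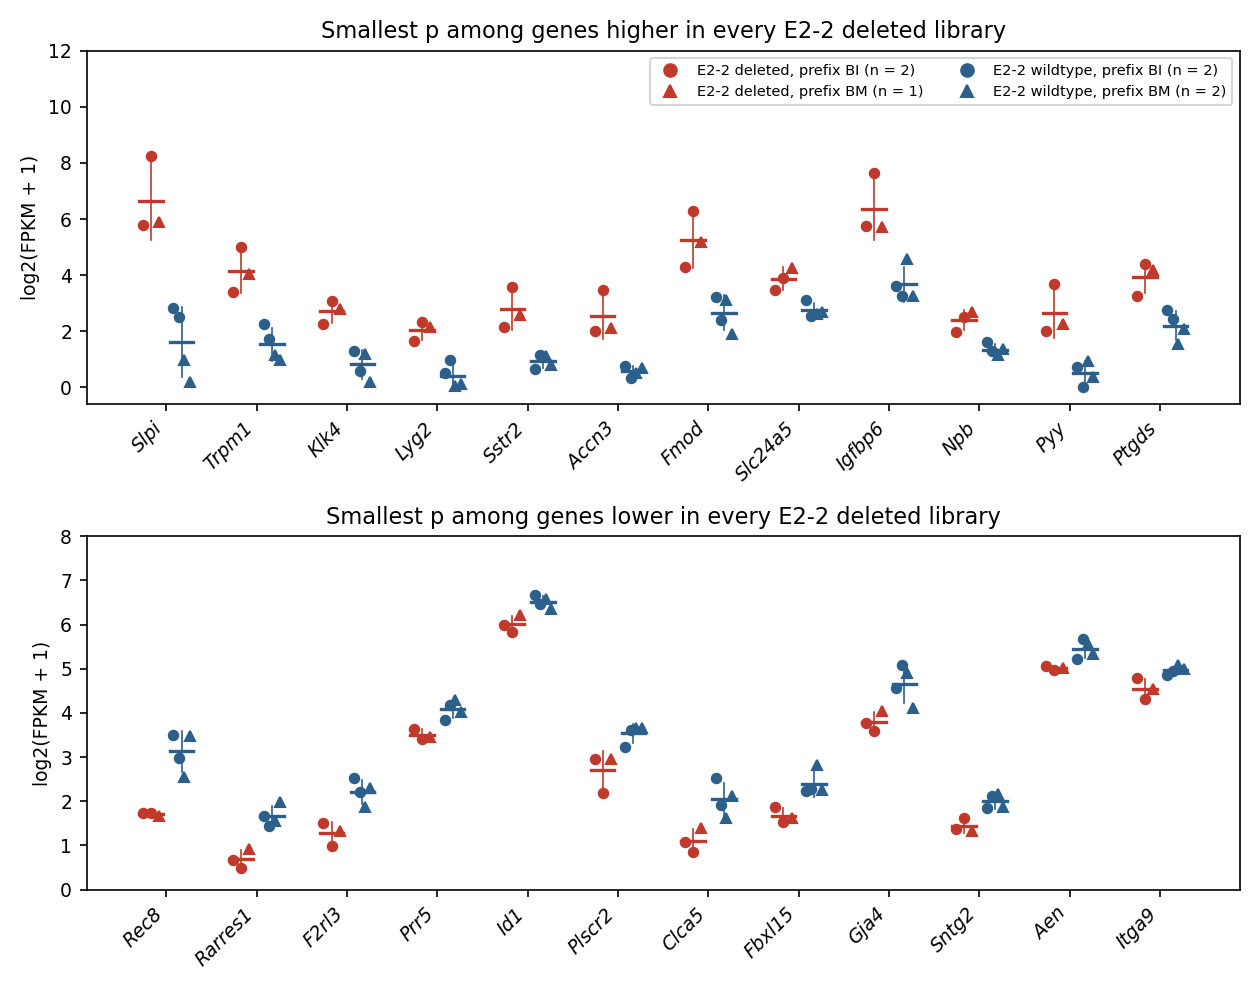
The 12 genes of smallest p among those higher (top) and lower (bottom) in all 3 E2-2 deleted libraries (red) than in all 4 E2-2 wildtype libraries (blue), as log2(FPKM + 1); circles are prefix BI, triangles prefix BM, and bars give the mean and SD of a genotype. The largest differences are 5.03 for Slpi and -1.42 for Rec8, and none of the 24 genes passed the threshold (adjusted p = 0.795).

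Transcripts of known Wnt/beta-catenin targets were higher as a group in the deleted libraries by camera at the preset correlation. This call was lost with an estimated correlation (adjusted p = 0.314) and by fry (adjusted p = 0.339). The exact permutation p was 0.210 adjusted over the 22 lists, a test that could pass only if many lists shared its smallest p. Axin2, a feedback inhibitor of the pathway (chromosome 11, 108781663 to 108812095), was at 55.0 ± 34.7 FPKM (SD, n = 3) against 21.2 ± 3.50 (SD, n = 4), a difference of 1.17 (SE 0.34; 1.23 within BI, 0.95 within BM). Wif1, a secreted Wnt inhibitor, was at 332 ± 250 against 61.8 ± 35.4, and Notum, an enzyme that inactivates Wnt ligands, at 115 ± 79.2 against 39.3 ± 9.09. The transcription factor genes Tcf7 and Lef1, partners of beta-catenin, were at 25.3 ± 10.8 against 12.5 ± 2.30 and at 12.3 ± 6.40 against 6.00 ± 1.32. Ctnnb1, which encodes beta-catenin and is not a member of the list, was at 576 ± 62.0 against 460 ± 56.2, a difference of 0.33 (SE 0.18; 0.17 within BI, 0.49 within BM).

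Of the 22 Wnt/beta-catenin targets tested, 20 had a positive difference, 9 at an unadjusted p under 0.05, and 10 were higher in every deleted library, where chance gives 2.86%. By limma 0 passed over all genes tested and 0 when adjusted over the list alone (smallest adjusted p = 0.0670). Their mean was 4.52 ± 0.41 (SD, n = 3) against 3.93 ± 0.16 (SD, n = 4), a difference of 0.58 (SE 0.22; 0.49 within BI, 0.64 within BM). Camera gave an adjusted p of 3.49e-10 at the preset correlation. The exact permutation p before adjustment was 0.0286, the smallest possible. Without E2-2 deleted replicate 2 the difference of the list was 0.37 (SE 0.15). Those of Axin2, Notum, Lef1 and Tcf7 then shrank from 1.17, 1.34, 0.84 and 0.90 to 0.70, 0.82, 0.47 and 0.59, and the mean of Wif1 in the deleted libraries was 193 FPKM. Tooth and enamel genes and melanocyte genes, in lists put together after the data had been seen, had higher means in the same libraries by 1.77 (1.17 within BI, 2.42 within BM) and 1.29 (0.68 and 2.14).

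Bone, muscle and other mesenchymal genes were also higher as groups at the preset correlation, and all 3 calls were lost with an estimated correlation (adjusted p = 0.314, 0.314 and 0.845). In the cartilage and bone list, 12 of 15 members had a positive difference and the mean difference was 0.59 (SE 0.22; 0.29 within BI, 0.93 within BM). The cartilage collagen genes of the list had no common direction. Col2a1 and Col9a1 were negative, at -0.99 (SE 0.75) and -0.59 (SE 0.33), as was the cartilage gene Lect1, at -0.22 (SE 0.22). Col11a1, Col9a2 and Col11a2 were positive, at 0.88 (SE 0.42), 0.24 (SE 0.19) and 0.06 (SE 0.23). Hapln1, a link protein of cartilage, was at 4.77 ± 0.655 FPKM (SD, n = 3) against 2.49 ± 0.554 (SD, n = 4). It was the 1 member that passed limma when adjusted over the list alone (adjusted p = 0.0420). The osteoblast factor gene Sp7 was at 15.6 ± 13.8 against 3.57 ± 1.71. The bone matrix gene Ibsp was at 28.9 ± 17.3 against 7.05 ± 11.1, and the alkaline phosphatase gene Alpl at 8.30 ± 2.48 against 4.07 ± 1.17. The camera adjusted p of the list was 1.23e-05 at the preset correlation. The mean of Ibsp in the wildtype libraries was 1.53 FPKM without wildtype replicate 1. The difference of Sp7 shrank from 1.6 to 0.95 without deleted replicate 2.

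Of the 27 genes in the skeletal muscle list, 10 were tested, and the muscle factor gene Myog was not among them. A positive difference was found in 7 of the 10, and the mean difference was 0.37 (SE 0.09; 0.45 within BI, 0.22 within BM). The myosin-binding protein gene Mybpc1 was at 47.0 ± 48.2 FPKM (SD, n = 3) against 9.10 ± 0.979 (SD, n = 4), and the slow troponin gene Tnni1 at 9.30 ± 2.37 against 4.70 ± 2.30. No member passed when adjusted over the list alone. In the mesenchyme and EMT list, 21 of 30 members had a positive difference and the mean difference was 0.16 (SE 0.21; 0.24 within BI, 0.04 within BM). The calcium-binding protein gene S100a4 was at 95 ± 52.4 against 19.2 ± 7.50 and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0366). The mesenchymal factor gene Prrx1 was at 43.7 ± 24.0 against 22.1 ± 6.61 and the filament gene Vim at 803 ± 78.0 against 924 ± 139. The camera adjusted p was 0.0289 for muscle and 0.0246 for mesenchyme, and with an estimated correlation the adjusted p was 0.314 and 0.845. The estimated correlations were -0.04 and 0.34, so the muscle call was not lost through a correlation above the preset 0.01. The muscle call was also lost with no filter (difference of 0.13, adjusted p = 0.210), quantile normalization (0.31, adjusted p = 0.167), a weight per library (0.24, adjusted p = 0.158) or sex as a term (0.37, adjusted p = 0.0747), and without deleted replicate 1, wildtype replicate 2 or wildtype replicate 4 (differences of 0.39, 0.34 and 0.36). The mesenchyme call was also lost with no filter (0.16, adjusted p = 0.0838) or a weight per library (0.14, adjusted p = 0.158). It was lost without wildtype replicate 1 or 4 (0.13 and 0.07) and without deleted replicate 2, where the difference was -0.00, and the difference was 0.28 without deleted replicate 1 or wildtype replicate 3. The differences of Mybpc1 and Prrx1 shrank from 1.76 and 0.84 to 0.96 and 0.44 without deleted replicate 2. Prrx1 differed by 1.28 without deleted replicate 1, and Vim by -0.13 without wildtype replicate 1 and -0.30 without wildtype replicate 4 (-0.19 with all libraries; -0.41 within BI, 0.11 within BM).

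Small positive differences of hypoxia, interferon and macrophage genes passed the same test, and the calls were lost with an estimated correlation (adjusted p = 0.620, 0.845 and 0.845). In the hypoxia and glycolysis list, 12 of 19 members had a positive difference, and the mean differed by 0.15 (SE 0.11; 0.10 within BI, 0.24 within BM). P4ha2, a subunit of a collagen prolyl hydroxylase, was at 24.6 ± 12.3 FPKM (SD, n = 3) against 14.5 ± 1.69 (SD, n = 4), the glucose transporter gene Slc2a1 at 33.3 ± 8.81 against 25.6 ± 1.14 and Bnip3, a mitophagy receptor, at 24.1 ± 9.53 against 14.1 ± 4.32. In the interferon list, 12 of 17 members had a positive difference, and the mean differed by 0.26 (SE 0.20; 0.10 within BI, 0.46 within BM). The antiviral genes Ifit1 and Ifit3 were at 3.01 ± 3.47 against 0.653 ± 0.204 and at 4.16 ± 4.19 against 1.54 ± 0.388, and Xaf1, an interferon-induced gene, at 3.64 ± 1.56 against 1.92 ± 1.66. In the macrophage list, 14 of 16 members had a positive difference, and the mean differed by 0.18 (SE 0.37; 0.04 within BI, 0.54 within BM). The mannose receptor gene Mrc1 was at 12.4 ± 2.92 against 9.13 ± 1.54, the chemokine receptor gene Cx3cr1, with a negative difference, at 1.18 ± 0.699 against 2.47 ± 1.37, and the chemokine gene Pf4 at 7.45 ± 3.37 against 4.03 ± 2.05. No member of the 3 lists passed when adjusted over the list alone. Camera adjusted p-values were 0.0150, 0.0246 and 0.0303.

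Processing choices and single libraries moved these 3 lists and their members. The interferon call was lost at a minimum of 5 FPKM (difference of 0.07, adjusted p = 0.313), with no filter (0.26, adjusted p = 0.0646) and with a weight per library (0.17, adjusted p = 0.138). The macrophage call was lost with median-of-ratios scaling (0.23, adjusted p = 0.0557) and with no filter (0.18, adjusted p = 0.0838), and the hypoxia call with a weight per library (0.14, adjusted p = 0.0658). The 3 calls were lost without deleted replicate 2 (differences of 0.09, 0.12 and 0.16) and without wildtype replicate 2 (0.11, 0.24 and 0.09), and the differences were 0.25, 0.44 and 0.43 without deleted replicate 1. The interferon call was also lost without deleted replicate 3 or wildtype replicate 3 (0.21 and 0.18). The macrophage call was also lost without wildtype replicate 4 (0.02) and without deleted replicate 3, where the difference was -0.04, and the difference was 0.40 without wildtype replicate 3. Ifit1 and Ifit3 were at 7.02 and 8.98 FPKM in deleted replicate 2. Without that library the differences of Ifit1, Ifit3, P4ha2, Slc2a1 and Mrc1 shrank from 0.95, 0.74, 0.62, 0.34 and 0.39 to 0.28, 0.12, 0.25, 0.14 and 0.26. Without deleted replicate 1 those of Ifit3, Bnip3 and Pf4 went from 0.74, 0.69 and 0.73 to 1.14, 1.06 and 1.12. Cx3cr1 went from -0.64 to -0.40 without wildtype replicate 3 and Xaf1 from 0.75 to 0.50 without deleted replicate 3. The mean of Cx3cr1 in the deleted libraries was 0.778 FPKM without deleted replicate 3, and that of Xaf1 in the wildtype libraries 1.10 FPKM without wildtype replicate 1.

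All 26 cell cycle genes tested had lower means in the deleted libraries, and this was the 1 list that passed the preset camera test in that direction. The call was lost with an estimated correlation (adjusted p = 0.845). The mitotic kinase gene Aurka was at 21.5 ± 5.35 FPKM (SD, n = 3) against 28.2 ± 3.77 (SD, n = 4). Cdc20, an activator of the mitotic ubiquitin ligase, was at 39.7 ± 13.7 against 57.3 ± 15.1. The replication helicase subunit gene Mcm5 was at 43.1 ± 13 against 56.9 ± 7.33 and the ribonucleotide reductase gene Rrm2 at 56.4 ± 8.18 against 67.3 ± 7.61. The mean difference of the list was -0.32 (SE 0.25; -0.29 within BI, -0.22 within BM; camera adjusted p = 1.23e-05). No member had an unadjusted p under 0.05, and none passed when adjusted over the list alone (smallest adjusted p = 0.302). Without deleted replicate 2 the difference of the list was -0.06, and those of Aurka, Cdc20, Mcm5 and Rrm2 shrank from -0.39, -0.55, -0.43 and -0.25 to -0.19, -0.23, -0.17 and -0.14.

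Nephron progenitor genes were low in 1 deleted library. Six2, which keeps progenitors of the nephron undifferentiated, was at 62.8, 2.69 and 33.5 FPKM in deleted replicates 1 to 3 against 53 ± 18.7 (SD, n = 4) in the wildtype libraries. The difference was -1.35 (SE 0.88; -1.40 within BI, -0.91 within BM), -0.13 without deleted replicate 2 and -2.18 without deleted replicate 1. Wt1, a factor of progenitors and podocytes, was at 37.9 ± 17.6 (SD, n = 3) against 50.6 ± 13.7 (SD, n = 4), a difference of -0.49 (-0.08 without deleted replicate 2, -0.80 without deleted replicate 1). In the cap mesenchyme list, which holds both, 17 of 20 members had a negative difference, and the mean differed by -0.41 (SE 0.43; -0.37 within BI, -0.30 within BM; camera adjusted p = 0.0926). Its members of smallest p were the homeobox genes Hoxa11, at 25.7 ± 3.92 against 30.4 ± 2.54, and Uncx, at 12.6 ± 10.7 against 25.7 ± 12.1, and the crystallin gene Crym, at 71.7 ± 9.79 against 52.9 ± 18.5. Uncx differed by -1.41 (-0.37 without deleted replicate 2; its mean in the deleted libraries was 7.75 FPKM without deleted replicate 1) and Crym by 0.50 (0.26 without wildtype replicate 3). The list differed by 0.04 without deleted replicate 2, and passed the preset test without deleted replicate 1 (-0.71) or wildtype replicate 2 (-0.56). With all 7 libraries it passed with median-of-ratios scaling (-0.37, adjusted p = 0.0442) or sex as a term (-0.47, adjusted p = 0.0298), and had an adjusted p = 0.845 with an estimated correlation.

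In the early nephron list, 14 of 17 members had a negative difference, and the mean differed by -0.25 (SE 0.21; -0.37 within BI, -0.12 within BM; camera adjusted p = 0.106). Fgf8, a growth factor of the renal vesicle, was at 1.74 ± 1.29 FPKM (SD, n = 3) against 3.88 ± 1.05 (SD, n = 4). Wnt4, which starts the epithelial transition of the progenitors, was at 60.0 ± 34.6 against 31.6 ± 3.62. In the proximal tubule list, 10 of 12 members had a negative difference, and the mean differed by -0.42 (SE 0.46; -0.98 within BI, 0.38 within BM; camera adjusted p = 0.106). The water channel gene Aqp1 was at 40.7 ± 39.8 against 14 ± 4.43, the zinc transporter gene Slc39a5 at 1.22 ± 0.853 against 3.01 ± 2.27 and the factor gene Hnf4a at 1.61 ± 1.24 against 4.11 ± 3.60.

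Both lists passed the preset test with all 7 libraries under other scalings, and neither kept its size in every subset of the libraries. Adjusted p-values were 0.0442 for both with median-of-ratios scaling (differences of -0.21 for early nephron and -0.38 for proximal tubule) and 0.0446 and 0.0274 with quantile normalization (-0.27 and -0.46). With an estimated correlation the adjusted p was 0.845 for both. The early nephron difference was -0.11 without deleted replicate 2 and -0.14 without wildtype replicate 2, against -0.39 without deleted replicate 1, and the list passed without wildtype replicate 3 (-0.34). The proximal tubule difference was -0.11 without wildtype replicate 2 and -0.26 without deleted replicate 1, and the list passed without deleted replicate 2 (-0.34), deleted replicate 3 (-0.64) or wildtype replicate 3 (-0.66). The differences of Fgf8, Wnt4 and Aqp1 shrank from -0.95, 0.77 and 1.09 to -0.46, 0.34 and 0.34 without deleted replicate 2. Without wildtype replicate 2 those of Hnf4a and Slc39a5 shrank from -0.84 and -0.77 to -0.42 and -0.43. Both were negative within BI (-1.69 and -1.55) and positive within BM (0.37 and 0.30), and their means in the deleted libraries were 0.893 and 0.727 FPKM without deleted replicate 3.

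The other lists of kidney cell types did not pass the threshold with all 7 libraries. The podocyte list (9 of 17 positive) differed by -0.07 (SE 0.29; -0.31 within BI, 0.17 within BM) and the ureteric bud list (10 of 20 positive) by -0.01 (SE 0.34; -0.23 and 0.25). The renal stroma list (11 of 23 positive) differed by -0.01 (SE 0.11; 0.06 and -0.05) and the epithelial junction and keratin list (15 of 25 positive) by 0.13 (SE 0.44; -0.12 and 0.35). Camera adjusted p-values were 0.374, 0.630, 0.619 and 0.121 in this order. Ren1, the renin gene and a member of the stromal list, was at 125 ± 128 FPKM (SD, n = 3) against 23.7 ± 14.5 (SD, n = 4), a difference of 2.02 (SE 0.66; 1.75 within BI, 2.05 within BM; 1.22 without deleted replicate 2). Cldn11, a claudin of the same list, was at 7.75 ± 2.98 against 12 ± 1.18. The podocyte factor gene Foxc2 was at 16.1 ± 6.33 against 24.0 ± 3.96 and the scaffold gene Magi2 at 1.72 ± 0.555 against 1.09 ± 0.276. In the ureteric bud list, the transporter gene Slco4c1 was at 1.37 ± 1.16 against 2.35 ± 0.929 and the factor gene Mecom at 22.1 ± 7.77 against 27.6 ± 4.23. In the epithelial list, the desmosome gene Dsp was at 11.9 ± 6.04 against 6.48 ± 3.44 and the membrane protease gene St14 at 18.5 ± 0.960 against 13.4 ± 5.62. Cdh1, which encodes E-cadherin, was at 28.1 ± 7.36 against 26.6 ± 12.9.

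Single libraries also moved these 4 lists and their members; with all 7 libraries and an estimated correlation the adjusted p was 0.845 for the podocyte, stromal and epithelial lists and 0.936 for the ureteric bud list. With 1 library left out, the differences ranged from -0.23 to 0.15 (podocyte), -0.25 to 0.19 (ureteric bud), -0.07 to 0.08 (renal stroma) and -0.21 to 0.28 (epithelial). The epithelial list passed without deleted replicate 3 (0.17), wildtype replicate 2 (0.26) or wildtype replicate 4 (0.28) and was negative without deleted replicate 1 (-0.04) or wildtype replicate 3 (-0.21). The podocyte list passed without wildtype replicate 2 (0.15) and the stromal list without wildtype replicate 3 (0.08). The ureteric bud difference was positive without deleted replicate 2 (0.19) or wildtype replicate 1, 2 or 4 (0.07, 0.03 and 0.11), and the stromal difference without deleted replicate 2 (0.03). Slco4c1 and Mecom were at 0.0255 and 13.2 FPKM in deleted replicate 2. Without that library the differences of Slco4c1, Mecom, Cldn11, Foxc2, Magi2 and Dsp shrank from -0.62, -0.36, -0.63, -0.61, 0.37 and 0.83 to -0.10, -0.04, -0.36, -0.28, 0.22 and 0.48. Without wildtype replicate 3 those of Dsp and St14 shrank from 0.83 and 0.55 to 0.48 and 0.20 and that of Cdh1 went from 0.23 to -0.23. Within BI and BM, Mecom differed by -0.72 and 0.19 and Cdh1 by -0.07 and 0.44. Mecom differed by -0.55 without deleted replicate 3, and Cdh1 by 0.03, 0.43 and 0.44 without deleted replicate 1, wildtype replicate 2 and wildtype replicate 4.

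Lists of the other cell types and programmes also did not pass with all 7 libraries. The endothelial list (10 of 18 positive) differed by 0.05 (SE 0.30; -0.43 within BI, 0.64 within BM). Its member Tek, an angiopoietin receptor gene, was at 9.94 ± 1.26 FPKM (SD, n = 3) against 5.43 ± 2.67 (SD, n = 4), and the endothelial factor gene Sox18 at 15.2 ± 3.22 against 25 ± 6.93. The neural and neural crest list (14 of 17 positive) differed by 0.29 (SE 0.67; -0.88 and 1.93), with the neural crest factor gene Sox10 at 2.10 ± 1.67 against 1.01 ± 1.02 and the factor gene Isl1 at 7.15 ± 4.37 against 4.31 ± 3.42. The erythroid list (2 of 6 positive) differed by -0.27 (SE 1.14; -1.83 and 2.46), with the globin genes Hbb-b2 at 2.62 ± 4.09 against 0.193 ± 0.386 and Hba-a2 at 4.08 ± 7.07 against 9.13 ± 8.50, which can share reads with near-identical copies, so that both levels are uncertain. The p53 target list (5 of 16 positive) differed by -0.08 (SE 0.10; -0.22 and 0.10), with Aen at 31.4 ± 0.956 against 43.0 ± 6.32, Phlda3 at 68.8 ± 6.2 against 88.4 ± 11.7 and the apoptosis genes Bbc3 at 8.69 ± 1.32 against 11.6 ± 1.05 and Perp at 21.8 ± 8.01 against 10.1 ± 6.48. The immediate early and heat shock list (7 of 17 positive) differed by 0.10 (SE 0.15; -0.01 and 0.16), with the anti-apoptotic gene Ier3 at 31.4 ± 15.7 against 15.4 ± 2.95 and the factor gene Klf4 at 15.7 ± 2.60 against 9.62 ± 3.04. The imprinted list (6 of 14 positive) differed by -0.05 (SE 0.11; -0.15 and 0.16), with the noncoding RNA gene Meg3 at 110.2 ± 28.4 against 83.9 ± 10.7 and the receptor gene Igf2r at 84.5 ± 28.4 against 65.9 ± 8.4. Camera adjusted p-values of these 6 lists were 0.256, 0.0674, 0.917, 0.106, 0.313 and 0.907. The gonad and adrenal list had 3 members above the filter and was not tested. Of these, Lhx9, a gonad factor, was at 1.97 ± 1.63 against 0.471 ± 0.320, the inhibin gene Inha at 4.19 ± 0.352 against 3.32 ± 0.657 and the steroidogenic gene Star at 2.33 ± 0.291 against 1.88 ± 0.391.

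Single libraries moved several of these 6 lists across the threshold or across 0; with all 7 libraries and an estimated correlation their adjusted p was 0.845 or more. The neural list passed with sex as a term (0.38, adjusted p = 0.0116) and without deleted replicate 1 (0.71), wildtype replicate 1 (0.65) or wildtype replicate 2 (0.39). It differed by -0.19 without deleted replicate 3, 0.07 without wildtype replicate 3 and 0.04 without wildtype replicate 4. The endothelial list passed without wildtype replicate 1 (0.18) or 2 (0.19) and was negative without deleted replicate 3 (-0.05), wildtype replicate 3 (-0.14) or wildtype replicate 4 (-0.01). The p53 list passed without deleted replicate 2 (-0.06) or wildtype replicate 4 (-0.10), and differed by -0.00 without wildtype replicate 2 and -0.13 without wildtype replicate 3. The immediate early list passed without wildtype replicate 2 (0.20) and differed by 0.07 without deleted replicate 2 and -0.00 without wildtype replicate 4. The erythroid difference was 0.78 without deleted replicate 2, 0.05 without wildtype replicate 1 and -1.43 without deleted replicate 3. The imprinted difference was 0.03 without deleted replicate 2 and -0.15 without deleted replicate 3. Median, mean and camera direction differed in sign for the podocyte, ureteric bud, renal stroma, erythroid, immediate early and imprinted lists.

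Several members of these lists also rested on single libraries. With 1 library left out, the difference ranged from 0.22 to 0.98 for Sox10, 0.30 to 1.08 for Isl1, 0.09 to 1.62 for Hbb-b2, -2.68 to -0.82 for Hba-a2 and 0.20 to 0.58 for Meg3. The differences of Sox10, Isl1, Hbb-b2 and Meg3 were smallest without deleted replicate 3, while that of Hba-a2 was largest in size without it. Those of Sox10, Hbb-b2 and Meg3 were largest without deleted replicate 1 and that of Isl1 without wildtype replicate 1; that of Hba-a2 was smallest in size without deleted replicate 1 or 2. Within BI and BM, Sox10 differed by -0.37 and 2.03, Isl1 by -0.45 and 2.27 and Hba-a2 by -3.93 and 2.29. Of the 3 deleted libraries, replicate 3 held most of the level of Hbb-b2 (7.34 FPKM) and Hba-a2 (12.2 FPKM). Without deleted replicate 2 the difference of Lhx9 shrank from 0.90 to 0.48, and without wildtype replicate 3 that of Star from 0.22 to 0.13. Those of Ier3 and Igf2r shrank from 0.90 and 0.31 to 0.53 and 0.06 without deleted replicate 2, and without wildtype replicate 3 that of Perp shrank from 1.19 to 0.79.

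Across the 22 lists, 8 passed camera at the preset correlation, 7 higher and 1 lower, and 0 passed with an estimated correlation and 0 by fry. By the adjusted exact permutation test 0 passed, but it could pass only if many lists shared its smallest p. At an unadjusted permutation p of 0.0286, the smallest possible, there were 3 lists, the Wnt/beta-catenin targets, skeletal muscle, and E proteins and Id factors. Without E2-2 deleted replicate 2 there were 7 lists past the preset camera test, 4 of them shared with the 8.

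**Figure D3:**
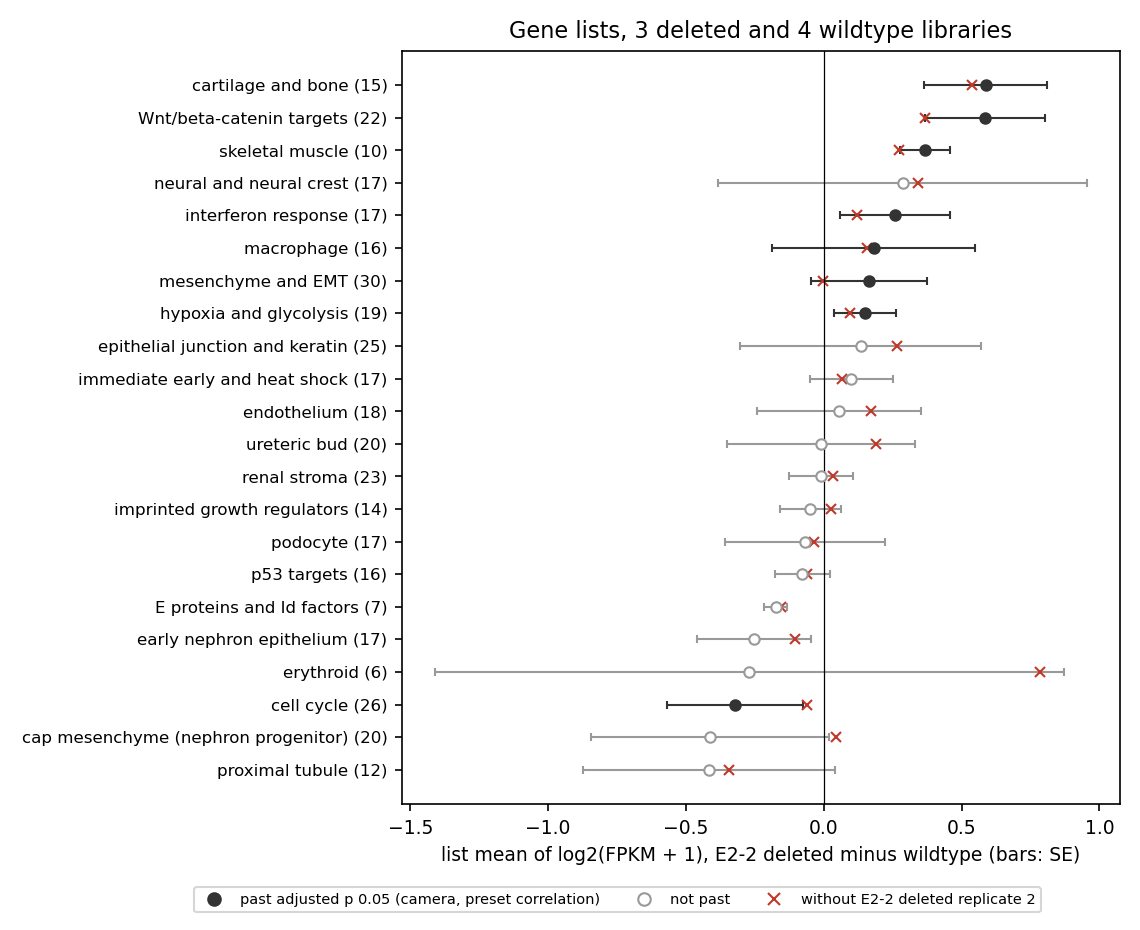
Mean log2(FPKM + 1) of each of 22 gene lists, E2-2 deleted minus E2-2 wildtype (circles; bars are SE, n = 3 and 4; number of tested members in brackets), with filled circles for lists past adjusted p 0.05 in camera at the preset correlation and crosses for the difference without E2-2 deleted replicate 2. The largest positive differences are cartilage and bone at 0.59 and Wnt/beta-catenin targets at 0.58, and the cell cycle difference of -0.32 shrinks to -0.06 without E2-2 deleted replicate 2.

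More genes differed between the prefixes than between the genotypes. Ribosomal protein genes were higher in the 3 BM libraries, at means of 7.98 to 8.38 on the log2 scale against 6.21 to 7.16 in the 4 BI libraries. The median difference was 1.39 over 79 genes (1.32 with median-of-ratios scaling and 1.09 with quantile normalization). Between the prefixes limma found 71 genes past adjusted p 0.05. Of these, 70 were higher in BM, 25 of them among the 79, and 1 lower, the mitochondrial leucyl-tRNA synthetase gene Lars2. The 79 were taken by symbol (Rpl or Rps with a number) and leave out other ribosomal protein genes. Of those left out, Rplp2 and Fau also passed and were higher in BM (1.93 and 1.81). With genotype as a term 43 genes passed, of which 19 are among the 79 and were higher in BM. Between genotypes the ribosomal protein genes had a median difference of -0.52 (-0.47 with median-of-ratios scaling, -0.38 with quantile normalization; -0.24 within BI, -0.35 within BM). It was -0.06 without deleted replicate 2, -0.93 without deleted replicate 3, and -0.82, -0.29 and -0.26 without wildtype replicates 2, 3 and 4. Libraries correlated at a mean r of 0.960 within genotypes and 0.952 between them, across genes, which are not independent replicates. That difference of 0.0081 ranged from -0.0037 without deleted replicate 2 to 0.0211 without deleted replicate 1; it was 0.0150 without deleted replicate 3, 0.0046 and 0.0013 without wildtype replicates 3 and 4, and 0.0037 with no filter on low values. The first principal component held 47.9% of the variance and set E2-2 deleted replicate 2 apart, whose mean r with the other libraries was 0.925. Xist, transcribed from the inactive X chromosome, was at 1.55 FPKM in E2-2 deleted replicate 1 and 1.13 in E2-2 wildtype replicate 4 and at 188 to 242 in the other 5 libraries. Those first-named libraries expressed Y-linked genes (Ddx3y at 32.3 and 36.0 FPKM).

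**Figure D4:**
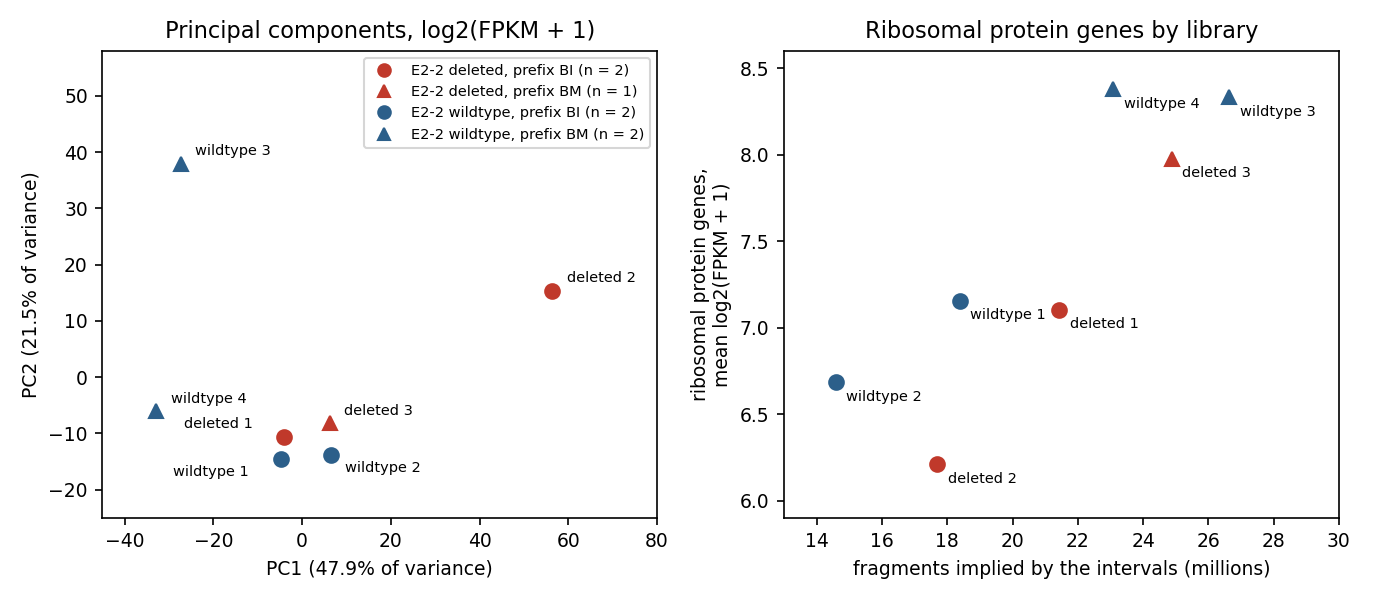
Left, the first and second principal components of log2(FPKM + 1) over 13466 genes (47.9% and 21.5% of the variance); right, mean log2(FPKM + 1) of ribosomal protein genes against the inferred depth in M (mega-fragments; the axis spells out the unit), for 3 E2-2 deleted (red) and 4 E2-2 wildtype (blue) libraries. E2-2 deleted replicate 2 stands apart on the first component at 56.4, and the 3 BM libraries (triangles) have the highest ribosomal protein means and depths.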

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

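Of the tests below, those of transcript length and GC content were chosen before their results were seen, and those of the splits, the prefix, a single library, depth, cell makeup and beta-catenin targets only after. In 10 of 145 results, 1 of the 4 wildtype libraries lay far from the other 3, where chance gives 7.25. The gap of that library to its nearest neighbour, as a share of the whole range, was 0.970 for Id3, 0.901 for Fbxl15, 0.971 for Krt19, 0.842 for Krt7 and 0.841 for the epithelial junction and keratin list in E2-2 wildtype replicate 3. Id3 and Fbxl15 were higher there and the others lower. The list mean in that library was 3.05, against 4.30 to 4.53 in the other 3. It was 0.867 for Id2 and 0.852 for Pdgfra in E2-2 wildtype replicate 2 (both lower), 0.887 for Plscr2 (lower) and 0.95 for Xaf1 (higher) in E2-2 wildtype replicate 1, and 0.999 for Hbb-b2 (higher) in E2-2 wildtype replicate 4.

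The 7 libraries can be split into 3 and 4 in 35 ways. The real split gave 0 genes past adjusted p 0.05 by limma (605 at an unadjusted p under 0.05); all 35 splits give at least 0, so this count cannot be tested against chance. Of the 35, 15 gave at least 605 genes at that unadjusted level, the highest other split giving 1964. At least 8 lists past the preset camera test came from 32 of the 35 splits, with 13 in the highest other split, so chance cannot be excluded for the counts of 605 genes and 8 lists. The split by prefix gave 71 genes past adjusted p 0.05 and was the 1 other split that gave any; with the prefix as a term the genotype comparison gave 0 genes by limma and 463 at an unadjusted p under 0.05.

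The Wnt/beta-catenin target list differed by 0.58 between genotypes, the largest size over the 35 splits (next 0.57), with an exact permutation p of 0.0286 that is 0.210 adjusted over 22 lists. With the prefix as a term the difference was 0.55 (SE 0.23), which argues against the prefix as its cause. Without E2-2 deleted replicate 2 it was 0.37 (SE 0.15). Both remaining deleted libraries (4.15 or more) lay above every wildtype library (4.13 or less), a gap too small to decide whether that library is the whole cause. The split with wildtype replicate 2 in place of deleted replicate 1 gave 0.57, close to the value of the real split. A candidate explanation is that loss of E2-2 raises transcripts of beta-catenin targets when beta-catenin is activated. Chance stays open. The adjusted permutation test cannot decide, since a list at the smallest possible p misses the threshold over 22 lists unless many others share that p. The preset camera call was lost with an estimated correlation (camera adjusted p = 0.314) and by fry (adjusted p = 0.339). Differences between kidneys in beta-catenin activation, days of culture and makeup of tissues stay open too, none of them tested. The tooth and enamel list and the melanocyte list, put together after the data were seen, differed by more (1.77 and 1.29).

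The ribosomal protein genes were higher in the 3 BM libraries by a median of 1.39 (1.32 with median-of-ratios scaling, 1.09 with quantile normalization). They exceeded other genes of matched transcript length by 1.21 (95% bootstrap interval 0.99 to 1.32) and of matched GC content by 1.35 (1.17 to 1.55). The bootstrap resampled ribosomal protein genes and not libraries, so these intervals measure the spread between genes. Both properties were those of the longest annotated transcript of a symbol, which need not be the one measured. Length therefore stays open, and across the other genes its rank correlation with the prefix difference was -0.338. That correlation was -0.088 for GC content, and the excess argues against GC content of that transcript as the whole cause. Depth cannot be told apart from the prefix, since the shallowest BM library was deeper by 1.66 M (mega-fragments) than the deepest BI library, although among the 4 BI libraries, too few to decide, the ribosomal protein mean did not keep the order of depth (6.68, 6.21, 7.16 and 7.10 at 14.6, 17.7, 18.4 and 21.4 M). The prefix holds both genotypes, and a difference in library preparation or sequencing run stays open, because the labels do not give one. No biological explanation was tested.

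E2-2 deleted replicate 2 stood apart on the first principal component (56.4). Lower depth is argued against by 1 library, E2-2 wildtype replicate 2, which was shallower and lay nearer to the rest. The nephron progenitor list of E2-2 deleted replicate 2 was the lowest of the 7 (3.06, next 3.94). A lower share of progenitors alone would raise the markers of every other cell type. However, 2 of 6 such lists were lower than the median of the other libraries by more than 1 SD (ureteric bud by -0.59, SD 0.40, and erythroid by -2.15, SD 1.03). The ureteric bud list was lower still in E2-2 wildtype replicate 3 (2.55, against 2.86), and the erythroid list rests on few genes. The macrophage, neural, renal stroma and endothelial lists differed from that median by 0.32, 0.30, -0.10 and -0.35, all within 1 SD. At most, the 2 low lists argue against a loss of progenitors that left the other cell types in their usual proportions. A loss of progenitors together with other cells stays open. The mean of Wnt/beta-catenin targets in E2-2 deleted replicate 2 was the highest of the 7, at 4.95 (next 4.45), which restates part of how this library differs and argues for no explanation. This library is itself E2-2 deleted and is 1 of 3; the response of this kidney and a difference in its culture both stay open, and neither was tested.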

How the results depend on the processing

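The fit with sex as a term, quantile normalization without ribosomal protein genes, the permutation test of list means, and all alternatives for the correlation between libraries were chosen only after the data were seen; the other alternatives were planned. The count of 0 genes by limma became 1 with no filter (Ndufs5) and 1 with a weight per library (9130015A21Rik), and was 0 in the other alternatives. Ndufs5 lies under the filter of 1 FPKM; for 9130015A21Rik the cause was not tested. The 605 genes at an unadjusted p under 0.05 became 1000 with no filter, 394 at a minimum of 5 FPKM, 1143 with a weight per library, and 250 to 1473 with 1 library left out. The 8 lists became 4 with no filter, 4 with a weight per library, 0 by camera with an estimated correlation and 0 by fry. The count was 0 by the adjusted exact permutation test, which could pass only if many lists shared its smallest p. Otherwise the count lay between 6 and 10. Of the values of single lists under an alternative, 28 lost the call, 27 gained it and 33 changed sign (2 of these also lost the call and 2 gained it); 311 did none of these.

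Signs changed as follows, and the cause was not tested. At a minimum of 5 FPKM the ureteric bud list was 0.031 and the podocyte list 0.077. With median-of-ratios scaling the ureteric bud list was 0.032, the renal stroma list 0.039 and the imprinted list 0.0026; with quantile normalization the renal stroma list was 0.052 and the imprinted list 0.061. With a weight per library Cdh1 was -0.0601, Hba-x 0.18 and Hbb-y 0.16, and the renal stroma list was 0.063, the epithelial list -0.061, the erythroid list 1.06 and the imprinted list 0.10. With the prefix as a term the renal stroma list was 0.014 and the endothelial list -0.0030. Within BI and BM, Hba-x differed by -1.62 and 1.63 and Hbb-y by -2.43 and 1.81. With 1 library left out, differences ranged from -0.30 to 0.030 for Tcf4, -0.23 to 0.44 for Cdh1, -1.05 to 0.58 for Hba-x and -1.82 to 0.62 for Hbb-y. The lists ranged from -0.71 to 0.043 (cap mesenchyme), -0.14 to 0.19 (endothelium), -0.21 to 0.28 (epithelial junction), -1.43 to 0.78 (erythroid), -0.0030 to 0.20 (immediate early), -0.15 to 0.026 (imprinted), -0.042 to 0.43 (macrophage), -0.0027 to 0.28 (mesenchyme and EMT), -0.19 to 0.71 (neural), -0.23 to 0.15 (podocyte), -0.069 to 0.075 (renal stroma) and -0.25 to 0.19 (ureteric bud). The Wnt/beta-catenin target, cartilage and bone, and cell cycle lists stayed past the preset camera test in every alternative that kept the preset test. The count-based test was not run, since the tables hold FPKM. The inferred depth of 14.6 to 26.6 M (mega-fragments) limits genes near 1 FPKM most.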

Other observations

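Some pigment cell and tooth genes were among the genes of smallest p with higher levels in the deleted libraries; both lists below were put together only after the genes of smallest p had been seen, so their values describe these libraries, and no test of either list is given. Of the 15 genes in the melanocyte list, 12 lay above the filter. Their median difference was 1.06 (1.11 with median-of-ratios scaling, 1.07 with quantile normalization). The melanin synthesis gene Dct was at 15.7 ± 8.57 FPKM (SD, n = 3) against 3.17 ± 2.44 (SD, n = 4), the pigment fibril gene Pmel at 15.6 ± 8.94 against 3.79 ± 2.57 and the melanosome gene Mlana at 16.6 ± 14.1 against 2.44 ± 2.28. The list mean differed by 1.29 (0.68 within BI, 2.14 within BM; 1.21 without E2-2 deleted replicate 2). The mean of Mlana was 8.57 FPKM in the deleted libraries without E2-2 deleted replicate 3 and 1.37 in the wildtype libraries without E2-2 wildtype replicate 1.

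Of the 16 genes in the tooth and enamel list, 10 lay above the filter. Their median difference was 1.82 (1.86 with median-of-ratios scaling, 1.8 with quantile normalization). Beside Ambn, Klk4 and Dspp, they are the signalling genes Wnt10a, Wnt6 and Bmp4, the factor genes Msx1, Msx2 and Dlx3, and Smpd3. The mean of such a list does not identify a tissue. The enamel matrix gene Ambn was at 20.2 ± 2.26 FPKM (SD, n = 3) against 3.06 ± 3.20 (SD, n = 4), the Wnt ligand genes Wnt10a and Wnt6 at 14.2 ± 8.44 against 3.03 ± 1.51 and at 29.9 ± 17.7 against 7.19 ± 3.51, and the sphingomyelinase gene Smpd3 at 41.0 ± 28.3 against 6.04 ± 5.33. The list mean differed by 1.77 (1.17 within BI, 2.42 within BM; 1.45 without E2-2 deleted replicate 2). The mean of Smpd3 in the deleted libraries was 26.2 FPKM without that library, and the means of Ambn and Smpd3 in the wildtype libraries were 1.58 and 3.62 without E2-2 wildtype replicate 1.

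A single gene passed the limma threshold in each of 2 alternatives and was named after its values were seen. Ndufs5, a subunit of mitochondrial complex I (chromosome 4, 123389953 to 123395429), was at 1.95, 2.39 and 2.26 FPKM in the deleted libraries. In all 4 wildtype libraries it was at 3.6e-05 to 3.8e-05 FPKM, which is 0 in effect, with almost no spread (SD 7.6e-07). Its mean of 0.942 lay under the filter of 1 FPKM, and with no filter its adjusted p was 0.000838, where the smallest adjusted p of the other alternatives ran from 0.0450 to 1.00; its exact permutation p was 0.0286, the smallest possible. The other 35 complex I subunit genes had a median of 85.6 FPKM and a lowest of 20.2, and a transcribed pseudogene of Ndufs5 is annotated, so its reads can be shared with a copy and its level is uncertain. 9130015A21Rik, a clone-named gene (chromosome 12, 36356963 to 36379790), was at 2.23, 2.87 and 2.40 FPKM in the deleted libraries and at 0.0724, 0, 0.449 and 0 in the wildtype libraries, with an adjusted p of 0.0450 with a weight per library and 0.732 without. At least 1 gene at 1 FPKM or more on one side and under 0.1 on the other occurred in 4 of the 35 splits.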
